A study of Mus musculus with 4 samples.

How the data were processed

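Total RNA from the livers of 2 wild type and 2 Cyp3a-/- mice was labelled with Cy3 and each sample was hybridised to its own 1-colour Agilent mouse expression array, per the labels. The genotype and replicate number of each array were taken from the labels, which speak of independent experiments with different animals but do not say whether a replicate number marks an experiment. Sex, age, strain and feeding state were not given in the sources used here. P-values of single genes rest in part on that gene's spread between these 4 livers and in part on the spread of all genes. The wild type livers share a slide, so their spread holds no difference between slides. The number of arrays, 2 per genotype, limits the precision of every value.

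The authors deposited each array as scanner output whose intensity values were extracted with Agilent Feature Extraction 11.5.1.1, per the submitters' processing notes and the file headers. The processed intensity of a spot is background-subtracted and detrended by that software and is not normalized between arrays, per the file headers. The files also hold the median pixel intensity of each spot and of its local background, and other columns hold flags of 0 or 1 for spots well above background, saturated or deviating, as deposited. The authors also deposited a table of log2 values for the same arrays, without stating its scale or centring. Set against the scanner values, that table behaved as log2 processed intensity minus the array's 75th percentile, centred on each probe's median over the 4 arrays. All 39417 probes in it had a median of 0 (tolerance 0.002), and each column correlated with the same array's scaled and centred scanner values at 1.00 after rounding. Scale, centring and direction of the table were inferred from this comparison. Its column medians were 0.06 and -0.07 for the wild type arrays and -0.02 and 0.02 for the Cyp3a-/- arrays, and 12 probes were not listed in it. No per-sample column was left unused (0 columns).

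Control spots were left out, as were between 113 and 148 spots per array that the scanner software marked as non-uniform or as population outliers. Signals were log2 processed intensity minus the 75th percentile of the array's 39429 non-control probes, and spots of one probe were averaged. A probe was kept when it was well above background on both arrays of at least 1 genotype, which held for 21508 probes. Probes were named by matching their RefSeq accession, without version, to a table of mouse genes of assembly GRCm38.p6. This named 28025 probes with 1 symbol and left 11404 without a symbol. Each gene was represented by its kept probe with the highest mean signal, which gave 17406 genes or other features, 13094 with a symbol and 4312 without. The array's design build is older than GRCm38.p6, so that table served for names and for neighbourhood, and no coordinates are given.

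Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), with Benjamini-Hochberg adjustment over all features and an adjusted p threshold of 0.05. The prior degrees of freedom were 3.54, beside 2 residual degrees of freedom. A gene's variance thus drew more on the spread of all genes than on its own. A gene not well above background on either array of a genotype has only a bound on its fold there. This "at least" fold set the mean of the brighter genotype against the mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. All log2 fold changes are Cyp3a-/- minus wild type. Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list's genes move on balance in one direction without comparing them with other genes. At its preset correlation camera compares genes with genes, so its p-values do not measure the spread between livers. List p-values were adjusted over the 31 lists. Members were counted over all genes and adjusted over the list alone. The share of changed genes near the cluster was compared with that of all other genes with a symbol by Fisher's exact test, 2-sided. Predicted genes were included and Cyp3a genes left out. This test, too, compares genes with genes.

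The samples, the tests, the lists, the rule for naming genes and most alternatives were set before the data were examined. The lists covered the Cyp3a cluster and its neighbours, cholesterol synthesis and uptake, bile acid synthesis, bile acid and sterol transport and sensing, targets of the receptors CAR and PXR, AhR, NRF2 and PPARA, fatty acid and triglyceride synthesis, gluconeogenesis and fasting, male- and female-biased liver genes, sex chromosome genes, the circadian clock, the acute phase, interferon, ER stress, the cell cycle, and markers of hepatocytes, pericentral and periportal hepatocytes, macrophages, stellate cells, sinusoidal endothelium, cholangiocytes, lymphocytes, neutrophils, erythroid cells, adipose tissue and exocrine pancreas. The rule named every Cyp3a gene; the 10 largest rises and falls among genes past the threshold whose arrays did not overlap between genotypes, leaving out Cyp3a genes and unnamed or predicted transcripts; where fewer than 3 fell, the 5 with the smallest unadjusted p in that direction; up to 4 members of each list by unadjusted p, or up to 3 of a cell type or sex list in which the list or a member passed; and the 3 genes within 5 Mb of the cluster with the smallest unadjusted p. Not every gene this rule allows is described.

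The alternatives were normexp background correction (offset 50), quantile normalization, median scaling, the authors' log2 values, no filter on dim probes, a filter requiring all 4 arrays, deviating spots kept, eBayes with an intensity trend and with a robust trend, the mean of a gene's probes, each probe on its own, the replicate number as a block, slide as a random block, windows of 2 and 10 Mb around the cluster, and leaving out each array. Chosen after seeing the data were the use of the spot median in normexp, because the files lack the spot mean that had been planned, a crossed replicate block, and an estimate of the slide correlation from the spread within each genotype, because limma's own estimate could not be had from 4 arrays. Camera takes neither a block nor a robust prior, so those settings were run with limma's cameraPR on the moderated statistics.

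The procedure was tested on simulated data for this comparison with 17406 genes. Of 50 genes changed by each amount, it recovered 4% at a log2 fold change of 1, 72% at 2, 98% at 4 and 100% at 8, and 8 of its 145 calls were false. A simulated list with a shift of 0.8 was called, as were 0 of 30 lists without a shift. The simulated genes varied independently of each other. The simulation thus says nothing of false calls among lists whose members vary together. Each simulated gene's variance was drawn from limma's fitted prior, whatever its signal, so the single-gene figures hold under limma's own model. Normalization, the background limit, the filter on dim probes and slides were not simulated.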

Results

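Gene expression was measured in the livers of 2 wild type mice and 2 mice lacking the Cyp3a cluster (Cyp3a-/-), 1 array per liver. Cyp3a genes encode the cytochrome P450 enzymes that oxidise many drugs and steroids in the liver. The comparison asks which transcripts differ in liver when this cluster is missing. Between 54.4% and 56.4% of probes were well above background on each array, no spot was saturated (0 on each array), and the 75th percentile of processed intensity lay between 308 and 352. Over the genes tested, the wild type arrays correlated with each other at 0.992 and the Cyp3a-/- arrays at 0.988, while arrays of different genotypes correlated at 0.977 to 0.987. By median absolute log2 difference the arrays did not group by genotype: Cyp3a-/- 2 differed from wild type 1 by 0.21 and from wild type 2 by 0.23, less than from Cyp3a-/- 1 (0.25), and the wild type arrays differed by 0.20. Both wild type arrays lay on slide 1, Cyp3a-/- 1 on slide 2 and Cyp3a-/- 2 on slide 3, all scanned on the same day, so slide follows genotype in every comparison.

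The Cyp3a transcripts were nearly absent from both Cyp3a-/- livers. Cyp3a11, the most abundant Cyp3a transcript of mouse liver, fell from 8.01 ± 0.11 to -6.96 ± 0.04 (log2 signal relative to the array's 75th percentile, SD, n = 2 per genotype; adjusted p = 1.4e-05). Its probe was not well above background in either Cyp3a-/- liver, so its level was at least 7204-fold lower. Cyp3a25 was at least 1721-fold lower (adjusted p = 2.2e-05), Cyp3a59 at least 1435-fold (adjusted p = 0.0018), Cyp3a16 at least 1044-fold (adjusted p = 3.3e-05), Cyp3a57 at least 750-fold (adjusted p = 2.3e-04) and Cyp3a41b at least 306-fold (adjusted p = 4.7e-05), each below background in both Cyp3a-/- livers. Cyp3a13, which lies on the same chromosome 5 outside the cluster and beyond the 5 Mb window around it, also fell, by 6.11 ± 0.18 (log2, SE), from 3.33 ± 0.14 to -2.78 ± 0.08 (SD, n = 2; adjusted p = 3.4e-04). Both Cyp3a13 probes stayed well above background in both Cyp3a-/- livers. Whether Cyp3a13 was itself targeted in these mice or fell for another reason cannot be told from these values. Cyp3a44 was not well above background on any array. As a list, the Cyp3a genes had 7 of 7 measured members lower over all genes and adjusted over the list alone (camera adjusted p = 5.8e-31; adjusted p = 0.608 with an estimated correlation). Their median log2 fold change was -11.95, or -10.03 with the genes below background set at their bound.

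Probes of one Cyp3a gene did not differ in direction, with fitted log2 fold changes of -12.34 and -14.97 for Cyp3a11, -7.46 and -11.95 for Cyp3a59 and -4.73 and -6.11 for Cyp3a13. The Cyp3a11 and Cyp3a59 probes were not well above background in either Cyp3a-/- liver. Their fitted sizes therefore cannot be compared between probes. Close copies such as Cyp3a41a and Cyp3a41b can share a probe's target, so the value given for Cyp3a41b is uncertain as that of a single gene. Without wild type 1 or without wild type 2, 6 of the 7 genes were called: Cyp3a59 missed the threshold, with an adjusted p of up to 0.115. With normexp, whose offset shrinks differences at low signal, all 7 were called at smaller folds (log2 -10.44 for Cyp3a11, -8.30 for Cyp3a25, -8.01 for Cyp3a59, -7.79 for Cyp3a16, -7.09 for Cyp3a57 and -5.48 for Cyp3a41b), so the bounds above hold for the processed intensity.

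**Figure D1:**
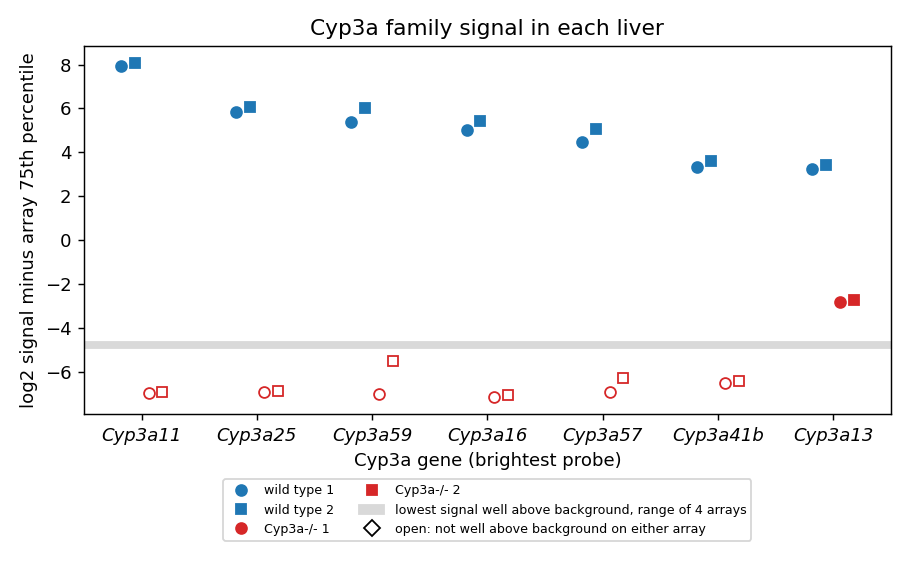
Log2 signal minus the array's 75th percentile (y axis) for the 7 measured Cyp3a genes (x axis, brightest probe), one symbol per liver, with blue for wild type and red for Cyp3a-/-. Open symbols mark genes not well above background on either array of that genotype, and the grey band spans the lowest signal well above background on the 4 arrays: 6 genes lie below it in both Cyp3a-/- livers, and Cyp3a13 stays above it.

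Outside the Cyp3a family, several drug-metabolism genes rose. Cyp2c55, a P450 of the Cyp2c family, rose by 5.39 ± 0.34 (log2 fold change, SE; 41.9-fold; adjusted p = 0.0086). Cyp2b10, the classic target of the xenobiotic receptor CAR, rose by 4.33 ± 0.23 (20.2-fold; adjusted p = 0.0040), from 1.36 ± 0.17 to 5.69 ± 0.30 (SD, n = 2). Cyp2b9, well above background on 1 of the 2 wild type arrays, rose 16.0-fold (adjusted p = 0.023), the aldo-keto reductase Akr1b7 by 3.31 ± 0.32 (adjusted p = 0.034), and the sulfotransferase Sult2a7 by 4.82 ± 0.31 (28.3-fold; adjusted p = 0.0088). Slco1a4, an uptake transporter of bile salts and drugs, rose by 3.15 ± 0.23 (8.85-fold; adjusted p = 0.014). Each of these 6 genes missed the threshold without wild type 1 and without wild type 2, with adjusted p of up to 0.131 for Cyp2b10, 0.106 for Cyp2c55, 0.194 for Sult2a7, 0.233 for Slco1a4, 0.292 for Cyp2b9 and 0.334 for Akr1b7. Their log2 fold changes moved little in these settings, the most for Cyp2c55, by 0.43 (4.96 without wild type 1 and 5.82 without wild type 2), and by 0.12 for Cyp2b10, 0.03 for Sult2a7, 0.14 for Slco1a4, 0.10 for Cyp2b9 and 0.04 for Akr1b7. With normexp background correction Cyp2b9 stood at 1.97 and Akr1b7 at 1.86, each with an adjusted p of 0.073, and Akr1b7 also missed the threshold with quantile normalization (adjusted p = 0.057). Without a filter on dim probes Cyp2b10 alone of the 6 passed.

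In all, 48 genes or other transcripts passed the threshold, 31 higher and 17 lower in Cyp3a-/- liver. All 48 had a fitted change of at least 2-fold, but with bounds for genes below background in a genotype 38 did, and for 10, Vipr2 among them, the bound was under 2-fold. Of the 41 outside the Cyp3a family, 31 rose and 10 fell. Among these, 19 carried no gene name or that of a predicted gene, and 22 were named genes, of which 20 rose and 2 fell. Several rises were of transcripts not well above background in either wild type liver, which held for 16 of the 31: Myom3, a muscle structural protein, was at least 62.8-fold higher (adjusted p = 0.025), the monooxygenase-like gene Moxd1 at least 49.8-fold (adjusted p = 0.017) and the transmembrane protein gene Tmeff2 at least 3.85-fold (adjusted p = 0.017). Xlr4b on chromosome X, well above background on 1 of the 2 wild type arrays, rose by 3.74 ± 0.31 (adjusted p = 0.019). The named genes that fell were Vipr2, a receptor for vasoactive intestinal peptide, at least 1.43-fold lower and below background in both Cyp3a-/- livers (adjusted p = 0.0082), and Ifitm7, which fell by 2.39 ± 0.17 (adjusted p = 0.014). Without a filter on dim probes another probe stood for Vipr2, at 0.21. With normexp the log2 fold changes were smaller and missed the threshold for Myom3 (3.22, adjusted p = 0.073), Tmeff2 (0.92, adjusted p = 0.151), Xlr4b (1.67, adjusted p = 0.078) and Vipr2 (-0.30, adjusted p = 0.545), while Moxd1 passed at 3.14 (adjusted p = 0.023). The bounds given for these genes thus hold for the processed intensity and not for normexp. The bound for Myom3 was 36.8-fold from Cyp3a-/- 1 alone and 107-fold from Cyp3a-/- 2 alone. The next lower genes by p did not pass: Serpina4-ps1 at -2.36 ± 0.27 (adjusted p = 0.061), Serpina9 at -1.85 ± 0.23 (adjusted p = 0.077) and Mthfd1l, below background in both Cyp3a-/- livers (adjusted p = 0.079).

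At an unadjusted p under 0.05, 1745 of 17406 genes differed, 801 higher and 944 lower. The arrays of the genotypes did not overlap for all 48 called genes and for 7441 of the 17406 genes, where chance alone would give 33.3%. Of the 41 genes called outside the Cyp3a family, nearly all missed the threshold when either wild type array was left out. All of them passed when either Cyp3a-/- array was left out. In such a fit the spread within a genotype came from the other genotype alone. The wild type arrays share a slide and the Cyp3a-/- arrays do not. The loss of calls thus need not mean a loss of the differences, and the log2 fold changes of the drug-metabolism genes above moved little. With normexp 34 genes were called, 16 of them among those 41, without a filter on dim probes 13, 6 of them among those 41, and with a filter requiring all 4 arrays 9, 8 of them among those 41. With slide as a random block 33 genes were called, 26 of them among those 41, and Myom3 and Akr1b7 missed the threshold.

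Targets of CAR and PXR, the receptors that switch on drug-metabolism genes, were higher as a group in Cyp3a-/- liver. Of 32 measured members, 6 rose, 0 fell and 26 did not pass over all genes; 20 rose and 1 fell adjusted over the list alone. The 6 were Cyp2b10, Cyp2c55, Slco1a4, Cyp2b9, Akr1b7 and Ces2a, a carboxylesterase named here after its values were seen (log2 fold change 1.76 ± 0.18, adjusted p = 0.040). The member that fell adjusted over the list alone was the efflux transporter gene Abcc4, at -0.55 ± 0.18. The list's median log2 fold change was 0.81, with 31 members above 0, and camera called it higher (adjusted p = 5.5e-21; adjusted p = 0.608 with an estimated correlation). Fry, which compares the list with no other genes, gave an adjusted p of 0.149 for one direction and 0.017 for either direction. The either-direction value is not particular to this list. Fry's adjusted p for either direction was also under 0.05 for lists that camera did not call. Among them were bile acid synthesis (0.033), bile acid and sterol transport and sensing (0.037) and the interferon response (0.048). It was 0.237 for the PPARA list and 0.190 for the cell cycle list. Of the 32 members, 8 also stand in other lists, Slco1a4 and Cyp2b9 among them.

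**Figure D2:**
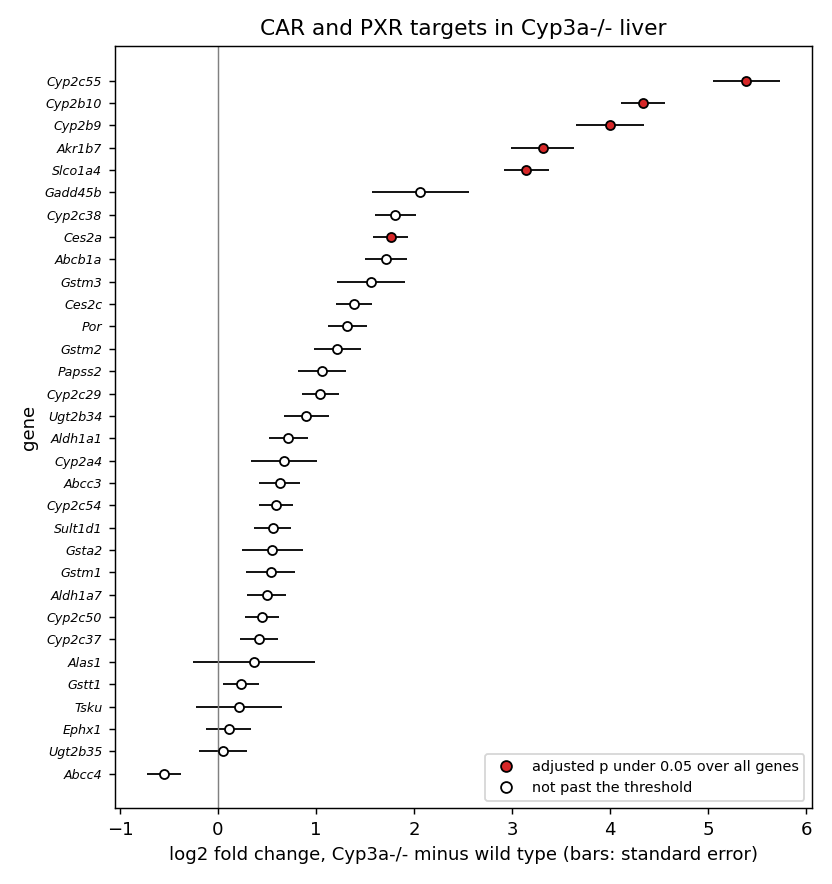
Log2 fold change in Cyp3a-/- against wild type liver (x axis; bars, standard error) for the 32 measured CAR and PXR targets (y axis). Filled points mark the 6 genes past the threshold over all genes, and 31 of 32 points lie above 0.

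PPARA targets and fatty acid oxidation genes, which the fasting receptor PPARA switches on, were lower as a group. None of the 28 members passed limma's threshold over all genes (0 rose, 0 fell; 9 at an unadjusted p under 0.05), and 3 fell adjusted over the list alone, namely the fatty acid transporter gene Cd36 at -1.41 ± 0.21, the hormone gene Fgf21, at least 5.81-fold lower and below background in both Cyp3a-/- livers, and Vnn1 at -1.66 ± 0.35. Cyp4a14, a fatty acid hydroxylase gene, stood at -3.96 ± 0.98 (adjusted p = 0.303). The list's median log2 fold change was -0.48, with 26 of 28 members below 0 (camera adjusted p = 7.3e-07; adjusted p = 0.913 with an estimated correlation). The bound for Fgf21 was 1.87-fold from wild type 1 alone and 18.1-fold from wild type 2 alone. Wild type 2 held the highest value for 25 of the 28 members. Without wild type 2 the median was -0.19 (camera adjusted p = 0.048), and without wild type 1 it was -0.83.

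Cell cycle genes were also lower as a group. Of 15 measured members none passed over all genes (0 rose, 0 fell; 8 at an unadjusted p under 0.05), and 2 fell adjusted over the list alone: Rrm2, a subunit of ribonucleotide reductase, at -1.93 ± 0.29, and cyclin E1 (Ccne1) at -0.83 ± 0.19. The proliferation marker Mki67 stood at -1.56 ± 0.49 (adjusted p = 0.396). The median was -1.04, with 14 members below 0 (camera adjusted p = 3.3e-06; adjusted p = 0.913 with an estimated correlation). Wild type 2 was highest for 14 of the 15, at a median of 1.18 above the mean of the 4 arrays, where wild type 1 lay at -0.11 and the Cyp3a-/- livers at -0.57 and -0.54. Without wild type 2 the median was -0.43 (camera adjusted p = 0.0032), and without wild type 1 it was -1.84.

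**Figure D3:**
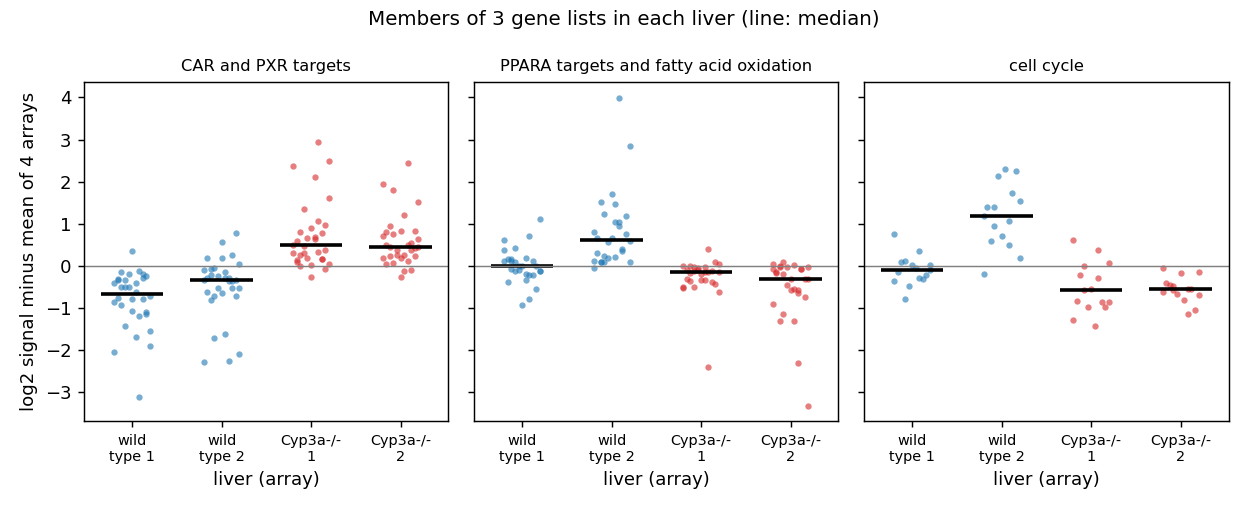
Log2 signal of each list member minus its mean over the 4 arrays (y axis) in each liver (x axis), for CAR and PXR targets, PPARA targets and cell cycle genes; the black line is the median of the members. Wild type 2 stands above the other livers for PPARA targets (median 0.62) and cell cycle genes (median 1.18), while both Cyp3a-/- livers stand above both wild type livers for CAR and PXR targets.

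Genes of sterol and bile acid metabolism, pathways that share substrates with Cyp3a enzymes, gave no list call with all 4 livers. For cholesterol synthesis and uptake, the Cyp3a-/- livers differed from each other: relative to the mean of the 4 arrays the median member lay at -0.38 in Cyp3a-/- 1 and at 0.36 in Cyp3a-/- 2, which was highest for 22 of 25 members, and at -0.03 and 0.01 in the wild type livers. Between genotypes, 0 of 25 members passed limma's threshold over all genes or adjusted over the list alone (0 at an unadjusted p under 0.05), and the median log2 fold change was 0.00 (camera adjusted p = 0.991). The list was higher without Cyp3a-/- 1 (median 0.42, camera adjusted p = 8.5e-07) and lower without Cyp3a-/- 2 (median -0.41, camera adjusted p = 4.3e-05). Dhcr7, the last enzyme of one branch of the pathway, stood at 0.45 ± 0.38 and Fdps at 0.33 ± 0.29.

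The lists of bile acid and fat metabolism were not called either. For bile acid synthesis, 0 of 15 passed over all genes (4 at an unadjusted p under 0.05), and 1 rose and 1 fell adjusted over the list alone (median 0.07, camera adjusted p = 0.427): Akr1d1, a reductase of bile acid precursors, at 1.75 ± 0.22 and Cyp39a1 at -1.26 ± 0.24. Cyp7a1, the rate-limiting enzyme, stood at 0.68 ± 0.21 (adjusted p = 0.389) and Cyp8b1 at 1.00 ± 0.32 (adjusted p = 0.406). Among 17 genes of bile acid and sterol transport and sensing, 1 rose, Slco1a4, over all genes and adjusted over the list alone (median -0.11, mean 0.10, camera adjusted p = 0.879), and Nr0b2, a repressor of bile acid synthesis, stood at -0.92 ± 0.26. For fatty acid and triglyceride synthesis, 0 of 22 passed either way (6 at an unadjusted p under 0.05; median -0.09, camera adjusted p = 0.327), with the fatty acid elongase gene Elovl5 at -0.91 ± 0.19 and the desaturase gene Scd1 at -0.79 ± 0.21. Without Cyp3a-/- 2 this list was called lower (median -0.19, camera adjusted p = 0.013). For gluconeogenesis and fasting, 0 of 14 passed either way (0 at an unadjusted p under 0.05; median 0.15, camera adjusted p = 0.427), with Pck1 at 0.40 ± 0.23 and G6pc at 0.38 ± 0.20.

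Stress and signalling lists were not called with all 4 livers. No AhR target passed (0 of 7, median -0.01, camera adjusted p = 0.991), with Cyp1a1 at 1.15 ± 0.53, and neither did any NRF2 target (0 of 16, median -0.07, camera adjusted p = 0.427), with G6pdx at -0.92 ± 0.19; both counts were also 0 adjusted over the list alone, with 0 and 3 members at an unadjusted p under 0.05. The same held for the circadian clock (0 of 14, median 0.14, camera adjusted p = 0.427) and the interferon response (0 of 16, median 0.10, camera adjusted p = 0.427), with 1 and 3 members at an unadjusted p under 0.05. For the acute phase response, 0 of 21 passed over all genes (2 at an unadjusted p under 0.05) and 2 adjusted over the list alone, the iron hormone gene Hamp, lower at -1.15 ± 0.22, and Orm3, higher at 1.55 ± 0.32 (median -0.05, camera adjusted p = 0.703). For ER and integrated stress, 0 of 17 passed over all genes (2 at an unadjusted p under 0.05) and 1 adjusted over the list alone, asparagine synthetase (Asns) at 2.14 ± 0.33 (median 0.23, camera adjusted p = 0.220). Without wild type 2 this list was called higher (median 0.32, camera adjusted p = 0.0062).

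Of the sex-biased lists, the male-biased genes had 1 of 17 past the threshold, Moxd1, and 2 adjusted over the list alone with Susd4 at 1.51 ± 0.24 (median 0.11, camera adjusted p = 0.162). The female-biased genes had 1 of 9, Cyp2b9, either way (median 0.67, camera adjusted p = 0.132), and the list was called higher without wild type 2 (median 0.53, camera adjusted p = 0.0027), with the replicate number as a block (median 0.67, camera adjusted p = 0.023) and with median scaling (median 0.71, camera adjusted p = 7.9e-05). Median scaling also called the male-biased list higher (median 0.15, camera adjusted p = 7.8e-04). Among 3 sex chromosome genes 0 passed over all genes (1 at an unadjusted p under 0.05) and 1, Uty at 1.23 ± 0.32, adjusted over the list alone (median 0.37, camera adjusted p = 0.162). Uty lay at -4.39 and -4.83 in the wild type livers, where the lowest signals well above background were -4.65 and -4.93. Ddx3y stood at 0.01 ± 0.19. In all 4 livers Ddx3y (1.33 to 1.57) and Eif2s3y (2.14 to 2.55) lay far above those lowest signals. Uty, Ddx3y, Eif2s3y and the members of cell type lists below were named after their values were seen.

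Cell type markers were not called in any list with all 4 livers, and 0 of 110 markers passed limma's threshold over all genes (14 at an unadjusted p under 0.05). This held for 13 hepatocyte markers (median 0.08, camera adjusted p = 0.851), 12 pericentral markers (median 0.05, camera adjusted p = 0.851), 13 periportal markers (median 0.10, camera adjusted p = 0.220), 12 macrophage markers (median -0.10, camera adjusted p = 0.220), 11 stellate cell and fibroblast markers (median -0.16, camera adjusted p = 0.132) and 11 sinusoidal endothelial markers (median -0.01, camera adjusted p = 0.851). It also held for 8 cholangiocyte (median 0.08, camera adjusted p = 0.851), 11 lymphocyte (median -0.08, camera adjusted p = 0.135), 4 neutrophil (median -0.03, camera adjusted p = 0.851), 7 erythroid (median -0.29, camera adjusted p = 0.213), 5 adipose (median 0.19, mean -0.02, camera adjusted p = 0.991) and 4 exocrine pancreas markers (median 0.12, camera adjusted p = 0.747). Adjusted over the list alone, 4 pericentral markers passed, in both directions (Oat at 1.04 ± 0.29 and Lect2 at 0.66 ± 0.19, Cldn2 at -0.80 ± 0.22 and Tbx3 at -0.68 ± 0.18). So did 3 erythroid markers, all globin genes (Hba-a1 at -1.07 ± 0.31, Hbb-b1 at -0.90 ± 0.26 and Hbb-b2 at -0.60 ± 0.18). The periportal Asl at 0.89 ± 0.18 and the macrophage Marco at -1.47 ± 0.30 passed as well. In the hepatocyte, stellate cell, sinusoidal endothelial, cholangiocyte, neutrophil, adipose and exocrine pancreas lists 0 members passed in this way. Stellate cell markers were called lower without wild type 2 (median -0.45, camera adjusted p = 0.018) and without Cyp3a-/- 2 (median -0.48, camera adjusted p = 0.036), and lymphocyte markers without wild type 2 (median -0.26, camera adjusted p = 0.0062).

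A knockout allele can carry neighbouring DNA of another mouse strain, so genes near the cluster were compared with the rest. Within 5 Mb of the cluster, 0 of 87 measured genes passed limma's adjusted threshold, Cyp3a genes left out. Of the other genes with a symbol, predicted genes included and Cyp3a genes left out, 27 of 13000 passed (Fisher's exact test, 2-sided, p = 1). At that share, 0 calls among 87 genes are likely anyway, so this count does not exclude an effect of carried DNA. At an unadjusted p under 0.05 there were 9 of the 87 (10.3%) and 1215 of the others (9.35%). Without Cyp3a-/- 1, 3 genes in the window were called, 4930449I24Rik, Gm3404 and Spdye4b, named after their values were seen. The smallest p-values in the window belonged to N4bp2l1 at 0.77 ± 0.18 (adjusted p = 0.277), Mm2pr at 1.14 ± 0.28 (adjusted p = 0.303) and 0610040B10Rik at 0.74 ± 0.20 (adjusted p = 0.332). The list of flanking genes fixed by name had 1 of 28 members past the threshold, over all genes and adjusted over the list alone (median 0.05, mean -0.15, camera adjusted p = 0.991). This was Cyp3a13, which is also counted in the Cyp3a list and lies beyond the window. Trrap stood at -0.37 ± 0.18 and Tmem130 was below background in both Cyp3a-/- livers. Of the 27 changed genes that could be placed, 2 lay within 5 Mb of another, Cyp2b9 and Cyp2b10, against a median of 4 in 10000 random gene sets of that size.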

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

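The crossed replicate block, the spot median in normexp and the estimate of the slide correlation were chosen only after the data were seen. Of the single-gene values set beside each alternative, 1362 kept their direction and their side of the threshold, 46 fell short of it, 46 newly passed and 5 changed sign. The sign changes were in genes not past the threshold, where leaving out 1 array gave -0.0992 to 0.994 for Dhcr7, -0.0567 to 0.709 for Fdps and -0.713 to 0.119 for Hsd17b7 (0.125 with normexp), and in Vipr2, at 0.210 without a filter on dim probes, when a brighter probe that the filter removes stood for it. The signs of Dhcr7, Fdps and Hsd17b7 followed which Cyp3a-/- liver was left out. The cause of the sign change of Hsd17b7 with normexp was not tested. The 48 calls became 659 with median scaling (641 at least 2-fold), where limma's prior degrees of freedom were infinite in place of 3.54, 34 with normexp (23 of them among the 48), whose offset shrinks differences at low signal, 13 without a filter on dim probes and 9 with all 4 arrays above background, a filter under which 18 of the 48 were tested and 1 Cyp3a gene in place of 7 was called. Leaving out 1 array gave 7 to 566 calls, for the count at a fitted 2-fold too. The lone array was then assumed to vary like the other genotype, whose arrays differed by a median of 0.25 for Cyp3a-/- and 0.20 for wild type. Near the cluster, 2 genes were called with median scaling (Bhlha15, Mm2pr) and 0 to 3 when an array was left out, and 0 with windows of 2 and 10 Mb. Of the 31 lists 4 were called; 4 to 8 when an array was left out, 6 with median scaling, 5 with the replicate block, 0 with an estimated correlation and 1 (Cyp3a) with fry. The estimated correlation gave adjusted p of 0.608 for the Cyp3a and for the CAR and PXR lists and 0.913 for the PPARA and cell cycle lists. Fry, counted here for one direction only, gave adjusted p of 0.149, 0.663 and 0.663 for the last 3. Camera's calls of these 4 lists held in all 18 alternatives (17 for Cyp3a, too few of whose members passed the filter on all 4 arrays), with adjusted p up to 9.6e-12 for CAR and PXR, 0.048 for PPARA and 0.0032 for the cell cycle. With the replicate number as a block, the replicate block fit called 58 genes, 43 of them among the 48. Differences of same-numbered arrays correlated at -0.10 across genes, so the numbers were not taken as pairs; with crossed numbers 56 genes were called. Splitting the 4 arrays 2 against 2 the other ways called 0 genes each, against 48 for genotype, with 321 and 540 at an unadjusted p under 0.05. Those splits put 1 array of each genotype in each group. A difference of genotype or slide then adds to the spread within groups, so fewer calls follow from the design. Besides, 3 splits are too few for a share under 0.05. Signal over background limits the folds of 16 called rises and 12 called falls to bounds.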

Other observations

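The tests of gene families, slides, pericentral markers, blood cell markers and fasting genes were chosen only after the results were seen. Camera called 9 of 14 families of genes with a common name higher in Cyp3a-/- liver, with p-values adjusted over the 14. Many members of these families also stand in the lists, among them 9 Cyp, 5 Gst, 2 Ugt and 1 Sult genes of the CAR and PXR list, so the families were tested again without any list's members. Called both ways were the sulfotransferases (Sult), with all 8 genes above 0 and a median log2 fold change of 0.61 (camera adjusted p = 1.0e-04; adjusted p = 0.354 with an estimated correlation), or 0.65 for the 7 outside the lists (camera adjusted p = 4.1e-04; adjusted p = 0.635 with an estimated correlation). So were the glucuronosyltransferases (Ugt), with 11 of 12 genes above 0 and a median of 0.33 (camera adjusted p = 0.0060; adjusted p = 0.471 with an estimated correlation), or 0.47 for the 8 outside the lists (camera adjusted p = 0.0046; adjusted p = 0.635 with an estimated correlation). These medians stayed above 0 in all 18 alternatives. The lowest were 0.39 for all Sult genes and 0.33 for those outside the lists, without Cyp3a-/- 2, and 0.08 for all Ugt genes and 0.24 for those outside the lists, without Cyp3a-/- 1. Sult2a7 alone of the Sult genes and 0 Ugt genes passed limma's threshold over all genes, where 3 of each family had an unadjusted p under 0.05.

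The other families called were ribosomal protein (Rpl and Rps), Gst, Akr, Ces, Aldh, Mup and Cyp genes outside Cyp3a. Of 92 ribosomal protein genes, 80 lay above 0 and 0 passed limma's threshold over all genes (2 at an unadjusted p under 0.05), with a median of 0.19 (camera adjusted p = 6.2e-06; adjusted p = 0.369 with an estimated correlation), or 0.02 with quantile normalization, the lowest of 18 alternatives. The 91 ribosomal protein genes outside the lists were called as well (median 0.19, camera adjusted p = 7.7e-06; adjusted p = 0.635 with an estimated correlation). The glutathione S-transferases (Gst, median 0.26, camera adjusted p = 0.0019), aldo-keto reductases (Akr, 0.25, camera adjusted p = 0.0034), carboxylesterases (Ces, 0.32, camera adjusted p = 0.0082), aldehyde dehydrogenases (Aldh, 0.19, camera adjusted p = 0.015), major urinary proteins (Mup, 0.18, camera adjusted p = 0.022) and Cyp genes (0.11, camera adjusted p = 0.022) were not called without the lists' members, with adjusted p of 0.107, 0.109, 0.205, 0.138, 0.070 and 0.928. With an estimated correlation these 6 had adjusted p of 0.354, 0.354, 0.389, 0.354, 0.580 and 0.354. With quantile normalization the medians were 0.13 for Gst, 0.16 for Ces and 0.04 for Aldh genes, and the Cyp median turned to -0.02. Leaving out 1 array took the median to 0.16 for Gst and 0.05 for Aldh genes without Cyp3a-/- 2, to 0.03 for Mup and 0.02 for Cyp genes without wild type 2, and to 0.21 for Ces genes without wild type 1. Slco, Abc, Serpina, histone and H2 genes were not called.

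The rise of CAR and PXR targets has 1 tested explanation that the data argue against and 1 that stays open. A larger share of pericentral hepatocytes, where many of these genes are most active, would raise other pericentral genes alike, but the 12 pericentral markers outside the list had a median log2 fold change of 0.0520 (SD 0.54), against 0.81 for the targets. The targets differed between the Cyp3a-/- arrays, which lie on different slides, by 0.315 times as much as between genotypes (median absolute difference 0.25 against 0.81). Both wild type arrays share a slide, so a shift of that slide and an effect of genotype cannot be told apart. As a hypothesis, loss of Cyp3a enzymes may leave substances that activate CAR or PXR at higher levels in liver, which was not tested.

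The lower PPARA targets may owe much of their size to a single wild type liver. Without wild type 2 the median log2 fold change was -0.19, and without wild type 1 it was -0.83 (with all 4 livers, camera adjusted p = 0.913 with an estimated correlation). A less fasted state of the Cyp3a-/- mice would lower fasting genes too. The 12 fasting genes outside the PPARA list had a median of 0.199 (SD 0.198), above 0 in all 18 alternatives but by more than their SD in 13, so this explanation was not excluded. The feeding state of the wild type mice and genotype itself stay open.

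The lower cell cycle genes were likewise lower by less without that liver: the median was -0.43 without wild type 2 and -1.84 without wild type 1, and the camera call held in both (with all 4 livers, adjusted p = 0.913 with an estimated correlation and 0.663 with fry). Fewer blood or immune cells in the Cyp3a-/- samples are argued against as the whole cause, since 22 lymphocyte, neutrophil and erythroid markers had a median of -0.0794 (SD 0.58), against -1.04 for the cell cycle genes. More dividing cells in the liver of wild type 2 is a candidate explanation that the values by liver are consistent with, and an effect of genotype stays open, since the medians of both Cyp3a-/- livers also lay below that of wild type 1.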
